A study of Drosophila melanogaster with 8 samples.

How the data were processed

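RNA sequencing libraries were made from adult muscle and from adult whole flies of Drosophila melanogaster, wildtype or labelled mutant, the mutant being a knockout of anw per the series' design text. There were 8 libraries in 4 groups of 2. Per the labels' protocols, flies were kept at 25 °C, RNA was purified on columns, and 1.3 µg of total RNA went into each mRNA library. The aligner, the counting tool, the treatment of strand and any filter on reads are not given in the sources used here. The submitters' processing notes name the mouse build mm10, but the deposited tables hold fly gene identifiers and coordinates of release 6 of the fly genome, so mm10 was not used. All coordinates are 1-based and are those of the deposited tables.

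The authors deposited 2 tables of FPKM, the reads of a gene per kilobase of its length and per library total in fixed units. The muscle table has 23983 entries with FlyBase identifiers, of which 5578 are transposable elements and 13968 are protein-coding genes. The whole-fly table has 17898 entries with NCBI identifiers, of which 13966 are protein-coding. Reference tables gave a symbol for 23366 and 17868 of them. Mitochondrial genes took their names from release 115 of the reference annotation by matching start, end and strand. Among the muscle entries, 5 gene names had been turned into dates and were replaced through their identifiers where possible, 538 entries had no symbol, and 26 had lost the number of their scaffold. The muscle columns name tissue, genotype and repeat. The whole-fly columns name only genotype and repeat, and were assigned to the whole-fly samples because the other table holds all 4 muscle samples. The 2 tables were made with different annotations and scaled separately, so each genotype effect was formed within a table. The interaction term and the alternative that shares the spread used the libraries of both tables in 1 fit, with the genotype effects still formed within each tissue.

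FPKM times gene length was a whole multiple of a single step per library for 100% of values above 0, within a tolerance of 0.1 reads. This gave between 18580751 and 22210197 reads per library. The total behind the deposited FPKM differed from those sums by a factor between 0.884 and 1.089, so the authors' values carry a scaling factor per library. A fold against libraries that all had 0 reads was computed against a floor of 3 reads per library and is a lower bound.

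The main test was limma 3.58.1 in R 4.3.3 (linear fit, moderated statistics with a mean-variance trend) on log2(FPKM + 1), for entries with FPKM of at least 1 in at least 2 of the 4 libraries of a tissue, with Benjamini-Hochberg adjustment at 0.05. Each tissue was fitted alone. Fold changes are mutant minus wildtype on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. The tests, the gene lists, the rule for named genes and the alternatives not said to be added later were chosen before the data were examined. A count model had been foreseen for raw counts, but the tables hold FPKM, so the test foreseen for FPKM was used. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists, and again with a correlation estimated from the residuals. The second check rests on the few degrees of freedom left between replicates. It can hardly call a list, also where the estimated correlation lies under the preset. Counts adjusted over the list alone treat each list as the whole family of tests. The difference of the genotype effect between tissues was the interaction term of a limma fit over all 8 libraries, for the 9465 genes that passed the filter in both tissues. Overlap of calls was tested with a 1-sided Fisher's exact test.

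The named genes were, per tissue, the 8 with the largest rise and the 8 with the largest fall among those that passed with both mutants on the same side of both wildtypes, up to 3 passing members of each list called by camera, up to 2 of each other list, and the 5 with the smallest interaction p. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing, and a called list without passing members is represented by the 2 with the smallest p. Genes outside this rule are said to have been chosen after their values were seen.

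The lists cover sarcomere proteins, flight muscle and tubular muscle isoforms, calcium handling and excitation, glycolysis, the tricarboxylic acid cycle, nuclear-encoded respiratory chain, the mitochondrial genome, cytoplasmic ribosome, proteasome, spliceosome, splicing regulators, antimicrobial peptides, Turandot stress peptides, heat shock, oxidative stress, cytochrome P450, glutathione transferases, insulin and FoxO, circadian clock, eggshell, ovarian germline, yolk proteins with female fat body, male accessory gland, testis, neuron, phototransduction, fat body, digestive enzymes of the gut, hemocyte, cuticle, odorant binding, trachea and autophagy. The lists of muscle isoforms share members with the sarcomere list.

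The model was tested on simulated reads with 50 genes changed at each of 4 sizes. Changes were planted only in more highly expressed genes, both groups had the same spread per gene, and noise was drawn independently between genes. The real muscle mutants were less alike than the wildtypes, so the shares recovered and falsely called need not hold for the real libraries. In the simulated muscle comparison, over 10190 entries, it recovered 4% of changes of 2-fold, 56% of 4-fold, 74% of 8-fold and 88% of 16-fold, and 5.1% of its calls were false. In the simulated whole-fly comparison, over 11335 entries, it recovered 62% of changes of 2-fold, 100% of 4-fold and 8-fold and 98% of 16-fold, with 3.7% false calls. With the same number of libraries, fewer small changes were recovered in muscle, where replicates were further apart.

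The alternatives were pseudocounts of 0.1 and 5, no filter and a minimum FPKM of 5, trimmed-mean and quantile scaling, moderation without a trend, a fit shared by both tissues, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were limma-voom on the recovered reads, scaling to the summed reads, protein-coding entries only, and a lowess trend of each library on log2 gene length, span 0.4, subtracted. When a library is left out, its partner is assumed to vary as the other group does. The filter was then applied again to the libraries kept. Genes that reached the minimum FPKM in the 2 libraries of 1 genotype alone were therefore not tested without either of these, and left their lists. A scan of medians over 15 neighbouring protein-coding genes was compared with 1000 shuffles of the fold changes over positions, and intervals of medians are 95% bootstrap intervals over genes from 10000 draws. Position scans, intervals and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

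Genes that share sequence with close copies, such as the trypsin cluster, the lysozymes, the actins, the Turandot genes and the drosomycin-like genes, carry uncertain values, because how the authors' counting divided shared reads is not given in the sources used here. The same holds for overlapping and antisense genes and for short mitochondrial genes that abut each other.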

Results

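Gene expression was measured by RNA sequencing in wildtype flies and in flies labelled as mutant, a knockout of anw, a gene that the series' title places among regulators of alternative splicing. Adult muscle and adult whole flies were profiled, with 2 wildtype and 2 mutant libraries of each. The tables give FPKM per gene, which measures total RNA of a gene and not its splice forms. Reads assigned to genes amounted to 21343286 and 19995132 in muscle wildtype, 18580751 and 20655630 in muscle mutant, 19332056 and 19624501 in whole-fly wildtype, and 22210197 and 20136878 in whole-fly mutant. The labels do not say whether repeats came from separate flies, so p-values measure only the spread between these samples, which may be technical.

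The targeted gene could not be followed. Neither deposited table nor the reference used here pairs the symbol anw with a gene, no other gene was assumed in its place, and the genotype labels were therefore not checked against RNA of the knocked-out gene.

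The first question was which genes differ between mutant and wildtype muscle. The gene w, which encodes the White transporter of eye pigment precursors, and the uncharacterised gene CG7916 showed the smallest p-values. The w gene (FBgn0003996, X, 2790599 to 2796466) had 2 and 1 reads in the wildtype libraries, 0.0398 and 0.0207 FPKM, and 1110 and 951 reads in the mutants, 23.3 and 22.1 FPKM. In whole flies w had 5 and 20 reads in wildtype and only 24 and 29 in mutant. Its rise was thus seen in the muscle mutants alone, and a difference of stock or samples cannot be told from an effect of the genotype. CG7916 (FBgn0028534, 2L, 13846752 to 13847799) stood at 0.608 and 0.475 FPKM in wildtype and 20.8 and 19.6 in mutant. In whole flies it was far higher, at 439 and 434 FPKM in wildtype and 371 and 295 in mutant. Whether RNA of other tissues gave its reads in mutant muscle was not tested. Lower values in mutants were led by CG7054, Pmm2, a phosphomannomutase gene, and short transcripts of the mitochondrial genome. No muscle gene passed the test after adjustment.

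By limma, 0 of 10079 entries were called in muscle, 1408 had an unadjusted p under 0.05, and limma-voom on the recovered reads also called 0. The differences of w, 4.53 ± 0.13 (log2, SE, n = 2 per group, limma adjusted p = 0.0545), and of CG7916, 3.78 ± 0.13 (limma adjusted p = 0.0558), lay just above the threshold. CG12057, CG31343 and CG17571 followed with log2 differences of 2.97, 2.72 and 2.02, all at an adjusted p of 0.167. On the lower side Pmm2 went from 37.5 and 31.3 FPKM to 5.24 and 6.05, a log2 difference of -2.41 ± 0.15, and CG7054 from 38.9 and 41.7 FPKM to 11.7 and 11.2. The mitochondrial mt:ATPase8 had a log2 difference of -1.98, mt:tRNA:Asp-GTC of -1.89 and CG34242 of -1.59, again at an adjusted p of 0.167. The 2 mitochondrial values rest on few reads, 55 and 55 against 10 and 11 for mt:ATPase8 and 17 and 15 against 3 and 3 for mt:tRNA:Asp-GTC.

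A minimum FPKM of 5, quantile scaling, protein-coding genes only or removal of a gene length trend each called 2 genes, w and CG7916, both higher. With either mutant left out these 2 genes no longer passed the filter and were not tested. Without mutant replicate 1 the count was 12, of which ClC-a, a chloride channel gene, was higher at 3.53 and 11 were lower, among them LysD at -5.49, CG14125 at -4.85 and CG10725 at -4.48. A fit that shared its spread with the whole-fly libraries called 267 muscle genes, 59 higher and 208 lower. The muscle mutants were less alike than the wildtypes, with a correlation of log2 values across genes of 0.878 against 0.973.

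At a preset correlation of 0.01, camera called 4 of 34 lists higher and 10 lower in mutant muscle, while in every list 0 members passed over all genes. These calls were made only at that preset. With an estimated correlation 0 lists were called, and the lowest adjusted p was 0.81. Spliceosome and antioxidant genes, with estimated correlations of -0.01 and -0.06, under the preset, lost their calls too. With so few libraries that check can hardly call a list, so it cannot tell whether correlation between genes made the calls.

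Genes of contraction and its control were among the higher lists. All 14 tested genes of calcium handling and excitation had positive values, with a median of 0.38 (log2) and a camera adjusted p of 9e-05, and adjusted p = 0.81 with an estimated correlation. RyR, the calcium release channel of the sarcoplasmic reticulum, had 24.2 and 26.9 FPKM in wildtype and 46.1 and 62.0 in mutant, and the sodium-calcium exchanger gene Calx a log2 difference of 0.55. None of these 14 passed when adjusted over the list alone. The muscle median was 0.19 without mutant replicate 2 (adjusted p = 0.0356, range over alternatives 1.7e-05 to 0.0356) and 0.59 without mutant replicate 1. Of 37 sarcomere genes 28 were positive and 9 negative, with a median of 0.27 (camera adjusted p = 0.0015, adjusted p = 0.81 with an estimated correlation) and 0 passing adjusted over the list alone. Msp300, a giant nuclear and Z-disc anchoring protein, had a difference of 1.08 and the troponin C gene TpnC47D of -0.76. The sarcomere call ended without wildtype replicate 1 (median 0.14, adjusted p = 0.0862) and without mutant replicate 2 (0.22, adjusted p = 0.0608), over alternatives that ranged from 8.02e-08 to 0.0862, and the median was 0.42 without wildtype replicate 2 and also without mutant replicate 1.

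Splicing factors went both ways. Of 44 splicing regulators 40 had positive values, with a median of 0.25 (camera adjusted p = 3e-05, adjusted p = 0.81 with an estimated correlation), and 0 passed adjusted over the list alone. The kinase gene Doa had a difference of 0.76 and the RNA-binding protein gene bol of 0.69. Core spliceosome genes were lower as a list, 26 of 37 negative, with a median of -0.17 (camera adjusted p = 0.021, adjusted p = 0.81 with an estimated correlation). Adjusted over the list alone, 3 spliceosome genes were lower. SmD1, a core snRNP protein gene, went from 10.9 and 7.94 FPKM to 2.91 and 2.70, and Sf3a2, of the U2 snRNP, from 17.8 and 18.3 to 6.47 and 5.85. Both lie in the 3L region of lower RNA given further on. The call of the regulators ended without mutant replicate 2 (0.12, adjusted p = 0.103) and with the gene length trend removed (0.13, adjusted p = 0.0674), in a range from 3.31e-08 to 0.103, and their muscle median was 0.4 without mutant replicate 1. The spliceosome call ended without wildtype replicate 1 (-0.12, adjusted p = 0.147), without mutant replicate 1 (-0.16, adjusted p = 0.106) and with the trend removed (-0.1, adjusted p = 0.0741), in a range from 0.00118 to 0.147, with a muscle median of -0.11 without mutant replicate 2.

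Most mitochondrial transcripts had lower values in mutant muscle, but their summed share of reads did not fall. Of 25 tested transcripts of the mitochondrial genome 23 were negative, with a median of -0.66 (camera adjusted p = 1e-07, adjusted p = 0.81 with an estimated correlation), and 5 were lower adjusted over the list alone. With protein-coding entries only, 13 muscle transcripts remained, with a median of -0.41 (adjusted p = 0.0011, range over alternatives 2.34e-10 to 0.00113). All mitochondrial transcripts together took 16.7% and 25.1% of reads in mutant muscle against 15.5% and 14.4% in wildtype, because of the large ribosomal RNA, and without ribosomal RNA 6.79% and 4.18% against 7.02% and 6.94%. Of 74 nuclear-encoded respiratory chain genes 56 were negative, with a median of -0.17 (camera adjusted p = 0.00029, adjusted p = 0.81 with an estimated correlation), but quantile scaling turned the median to 0.08 (adjusted p = 0.218) and removal of the length trend left -0.02 (adjusted p = 0.442), in a range from 5.09e-06 to 0.442. The complex I genes ND-SGDH and ND-B17 had differences of -0.79 and -0.59. ND-SGDH lies in a stretch of lower muscle RNA on 3L, given under other observations. Of 18 genes of the tricarboxylic acid cycle 15 were negative, with a median of -0.18 (camera adjusted p = 0.0094, adjusted p = 0.81 with an estimated correlation), which quantile scaling turned to 0.02 (adjusted p = 0.965). That call also ended without wildtype replicate 2 (-0.14, adjusted p = 0.0945), without mutant replicate 2 (-0.17, adjusted p = 0.06) and with the trend removed (-0.13, adjusted p = 0.0674), in a range from 0.000283 to 0.965, and the muscle median was -0.27 without wildtype replicate 1. SdhC, a subunit of succinate dehydrogenase, went from 1054 and 877 FPKM to 602 and 684, and isocitrate dehydrogenase gene Idh had a difference of -0.55. In both nuclear lists 0 members passed adjusted over the list alone.

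Detoxification and immune gene lists were called lower in mutant muscle at the preset correlation, where RNA of digestive enzymes (2.22% and 1.41% of reads against 2.75% and 3.38% in wildtype) and of fat body genes (0.668% and 0.593% against 0.837% and 0.738%) was lower as well. Of 56 cytochrome P450 genes 44 were negative, with a median of -0.21 (camera adjusted p = 0.00027, adjusted p = 0.81 with an estimated correlation), and 4 were lower adjusted over the list alone. Cyp6g2 had a difference of -1.27 and Cyp4e1 of -1.19. The muscle median was -0.12 without wildtype replicate 2 (adjusted p = 0.0346, range over alternatives 4.26e-07 to 0.0346) and -0.34 without wildtype replicate 1 or mutant replicate 1. Of 28 glutathione transferases 22 were negative, with a median of -0.44 (camera adjusted p = 3e-04, adjusted p = 0.81 with an estimated correlation) and 0 adjusted over the list alone, and GstD9 stood at -1.31 and GstE9 at -1. With the length trend removed their median was -0.25 (adjusted p = 0.0674, range 4.23e-10 to 0.0674), and without wildtype replicate 2 it was -0.23 in muscle. Of 25 antimicrobial peptide genes 15 were negative, with a median of -0.41 (camera adjusted p = 0.0085, adjusted p = 0.83 with an estimated correlation) and 1 lower adjusted over the list alone. The drosomycin-like gene Drsl4 went from 65.8 and 55.4 FPKM to 4.89 and 7.80, and BomBc2 had a difference of -1.11. Their median was -1.04 without wildtype replicate 1 and -0.83 without mutant replicate 2. The call ended without wildtype replicate 2 (-0.22, adjusted p = 0.969) and without mutant replicate 1 (-0.27, adjusted p = 0.179), in a range from 1.2e-09 to 0.969.

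The remaining called muscle lists covered the proteasome, antioxidants, odorant binding and neurons. Proteasome genes had a median of -0.2 with 33 of 40 negative (camera adjusted p = 0.026, adjusted p = 0.85 with an estimated correlation), with Prosalpha4 at -0.57 and Rpn11 at -0.39, antioxidant genes a median of -0.18 with 15 of 18 negative (0.027, adjusted p = 0.81 with an estimated correlation), with GstD1 at -0.87 and Sod1 at -0.56, odorant binding proteins -0.32 with 16 of 20 negative (0.013, adjusted p = 0.81 with an estimated correlation), with Obp57b at -0.47 and Obp57a at -0.39, and neuronal genes 0.21 with 16 of 19 positive (0.018, adjusted p = 0.85 with an estimated correlation), with the GABA receptor gene Rdl at 0.83 and ChAT at 0.29. In these 4 lists 0 members passed adjusted over the list alone. Without mutant replicate 2 all 4 calls ended, with the proteasome at 0.02 (adjusted p = 0.4), antioxidants at -0.21 (adjusted p = 0.0608), odorant binding at -0.27 (adjusted p = 0.259) and neurons at 0.05 (adjusted p = 0.81). Without wildtype replicate 1 the proteasome was at -0.12 (adjusted p = 0.231), odorant binding at -0.26 (adjusted p = 0.139) and neurons at 0.19 (adjusted p = 0.0859). Without mutant replicate 1 the muscle medians were -0.38 for the proteasome and 0.39 for neurons. Antioxidants also lost their call without wildtype replicate 2 (-0.19, adjusted p = 0.0746) and without mutant replicate 1 (-0.15, adjusted p = 0.125). Across alternatives the adjusted p ranged from 4.47e-06 to 0.546 for the proteasome, 0.00177 to 0.555 for antioxidants, 0.00174 to 0.259 for odorant binding and 6.31e-05 to 0.909 for neurons.

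Of the 14 lists called in muscle, 9 kept call and direction without wildtype replicate 1, 11 without wildtype replicate 2, 11 without mutant replicate 1 and 7 without mutant replicate 2. Fold changes rose with gene length in muscle, with a Spearman correlation of 0.33 across 9465 genes, which are not independent replicates, and medians of -0.17 in the shortest eighth and 0.22 in the longest. Against the wildtype mean the correlation was 0.19 for mutant replicate 1 and 0.46 for mutant replicate 2. A length trend also separated libraries of the same genotype, at 0.26 for wildtype replicate 2 minus 1 and 0.24 for mutant replicate 2 minus 1. With that trend removed 5 of the 14 lists kept their call. Their medians went from 0.38 to 0.25 for calcium handling and excitation, 0.27 to 0.22 for the sarcomere, -0.66 to -0.57 for the mitochondrial genome, -0.21 to -0.12 for cytochrome P450 and -0.41 to -0.2 for antimicrobial peptides (adjusted p = 0.048).

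The other lists were not called in muscle. Medians were -0.14 for glycolysis (adjusted p = 0.061), -0.12 for the cytoplasmic ribosome (0.059), 0.29 for insulin and FoxO genes (0.061), -0.69 for cuticle (0.061), -0.34 for fat body (0.086), -0.35 for digestive enzymes (0.086), 0.32 for phototransduction (0.086), -2.29 for eggshell (0.11), -0.61 for yolk proteins (0.34), 0.17 for Turandot genes (0.35), 0.25 for tubular muscle isoforms (0.44), 0.24 for heat shock (0.44), -0.69 for ovarian germline (0.59), -0.44 for trachea (0.59) and -0.04 for hemocytes (0.97). Quantile scaling turned glycolysis to 0.07 and the ribosome to 0.1, at which the muscle ribosome list was called higher (adjusted p = 0.014). The ribosome list was lower at -0.34 without mutant replicate 2 (adjusted p = 1.5e-08) and at -0.23 without wildtype replicate 2 (adjusted p = 0.00027), but had 0.12 without mutant replicate 1 (adjusted p = 0.05) and 0.01 without wildtype replicate 1 (adjusted p = 0.9), so single libraries set its direction. Its adjusted p ranged from 1.5e-08 to 0.9. Single libraries also moved other muscle lists. Eggshell genes had 0.44 without wildtype replicate 1 and were called at -4.52 without wildtype replicate 2, and digestive enzymes had 0.06 without mutant replicate 2 and were called at -0.81 without mutant replicate 1. Calls arose without mutant replicate 1 for cuticle (-1.16), insulin and FoxO (0.44) and phototransduction (0.59), without wildtype replicate 2 for fat body (-0.57) and yolk proteins (-1.04), and without wildtype replicate 1 for Turandot genes (0.44). Medians, means or tests differed in sign for flight muscle isoforms (-0.01, adjusted p = 0.66), circadian clock (0.05, 0.97), autophagy (0.07, 0.76), accessory gland (-0.08, 0.76) and testis (-0.01, 0.63). Adjusted over the list alone, passing members were 3 higher and 6 lower for digestive enzymes, 1 higher and 2 lower for heat shock, 2 lower for autophagy, 1 lower each for tubular isoforms and clock genes, and 1 higher each for flight isoforms and Turandot genes. In the remaining lists there were 0.

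The muscle libraries held different amounts of RNA from other tissues. Testis genes took 0.188% of reads in mutant replicate 1, 0.0148% in mutant replicate 2, and 0.0534% and 0.0238% in the wildtypes, and accessory gland genes 0.0389%, 0.0032%, 0.0143% and 0.00699% in the same order. Without mutant replicate 1 the testis list had a median of -2.65 and without mutant replicate 2 of 2.16. Eggshell genes took 0.0705% and 0.0212% of reads in wildtype muscle and 0.000786% and 0.005% in mutant muscle. Digestive enzyme genes took larger shares, with 2.75% and 3.38% in wildtype muscle and 2.22% and 1.41% in mutant muscle, and yolk and female fat body genes 4.58% and 2.53% in wildtype and 1.55% and 2.97% in mutant muscle. The mitochondrial large ribosomal RNA took 20.84% of reads in mutant replicate 2 and 9.84% in mutant replicate 1, against 8.33% and 7.37% in wildtype.

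**Figure D1:**
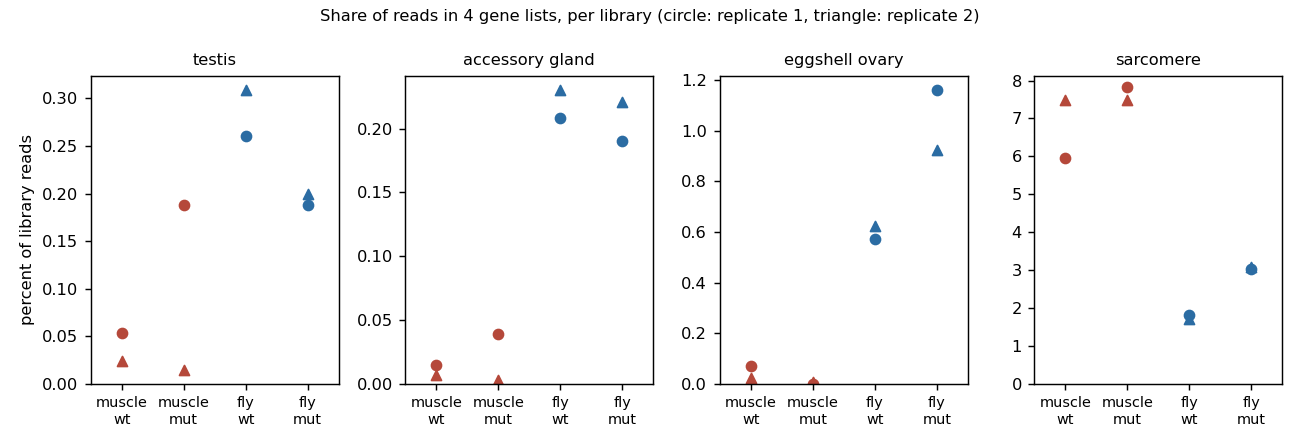
Percent of each library's reads (vertical axes, each with its own scale from 0) in the testis, accessory gland, eggshell and sarcomere lists, for muscle (red) and whole-fly (blue) libraries, with a circle for replicate 1 and a triangle for replicate 2. Muscle mutant replicate 1 stands at 0.188% for testis genes against 0.0148% in replicate 2, and sarcomere genes take 3.03% and 3.09% of reads in whole-fly mutants against 1.81% and 1.71% in wildtype.

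A run of neighbouring genes on chromosome arm 3L was lower in both muscle mutants, a feature chosen after the values were seen. Between 12486668 and 13301922 (release 6) lay 66 tested protein-coding genes, of which 62 had negative log2 differences and 53 were below the wildtype mean FPKM in both mutants. The median mutant to wildtype ratio was 0.462, with a 95% bootstrap interval over genes of 0.398 to 0.554, and was 0.439 in mutant replicate 1 and 0.387 in mutant replicate 2. Pmm2, CG34242, Sf3a2 and SmD1 lie inside it. The gene sti, encoding citron kinase, which also lies inside it, went the other way, from 0.269 and 0.224 FPKM to 2.74 and 2.29. In whole flies the same 66 genes had a median ratio of 1.0 (0.906 to 1.067). No single gene of the region was called.

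**Figure D2:**
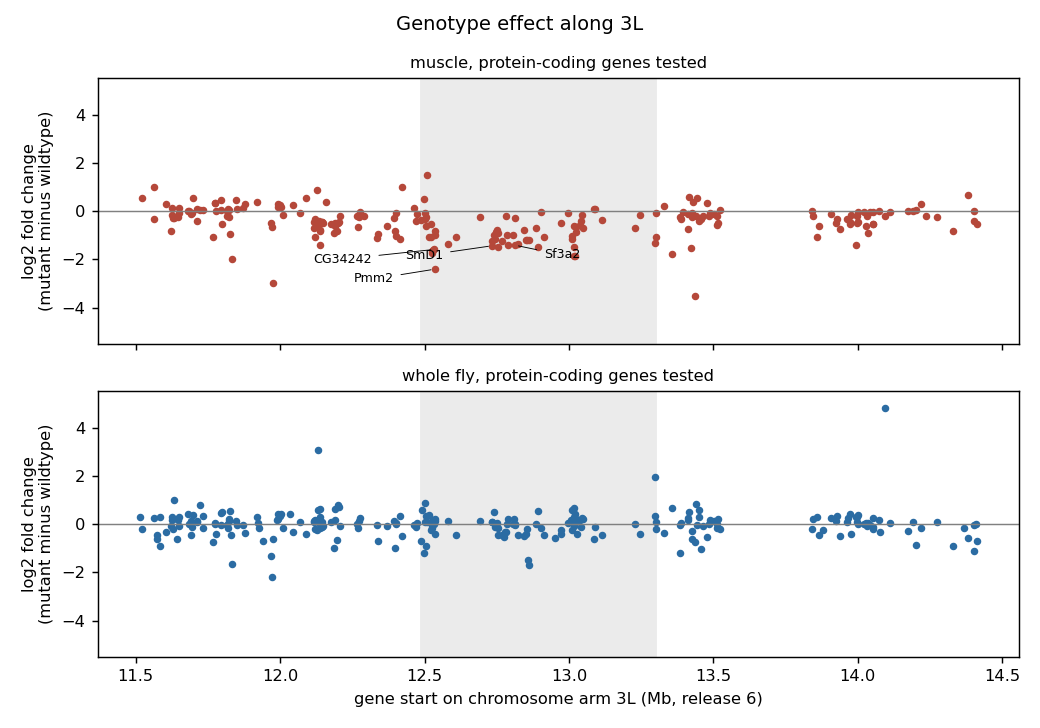
Log2 fold change of each tested protein-coding gene (vertical axis, mutant minus wildtype) against its start on chromosome arm 3L in megabases (horizontal axis), in muscle (upper panel) and whole flies (lower panel), with the region from 12486668 to 13301922 shaded. In muscle 62 of the 66 genes in the shaded region lie under 0, and in whole flies their median ratio is 1.0.

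The second question was which genes differ between mutant and wildtype whole flies. Among the lists called higher at a preset correlation were those of muscle contraction, energy metabolism, eggshell and cuticle, and among those called lower were digestive enzymes, antimicrobial peptides, Turandot stress peptides and testis genes. In most of these lists part of the members did not pass, and with an estimated correlation 0 lists were called, the lowest adjusted p being 0.45. The cuticle protein gene Cpr92F (42450, 3R, 20669571 to 20672821) rose from 2.34 and 1.93 FPKM to 221 and 216, a log2 difference of 6.13 ± 0.11 (SE, n = 2 per group, limma adjusted p = 8.34e-07). The trypsin gene gammaTry (36221, 2R, 11349061 to 11349870) fell from 206 and 201 FPKM to 4.40 and 4.11, a log2 difference of -5.28 ± 0.10 (limma adjusted p = 8.34e-07).

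By limma, 2372 of 11419 entries were called, 1135 higher and 1237 lower, so that 47.8% of calls were higher. Scaling to the summed reads instead gave 2609 calls, 856 higher and 1753 lower, with 32.8% higher, and moved the median of all genes from 0.022 to -0.089. Without wildtype replicate 1 there were 1409 calls and without wildtype replicate 2 there were 1512, and a fit sharing its spread with muscle called 546. Replicates were close, with correlations of log2 values across genes of 0.991 in wildtype and 0.99 in mutant.

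Among the largest rises were genes of the male seminal fluid, of larval and adult fat body and of the gut. Acp54A1, a seminal fluid gene, had 0 reads in both wildtypes and stood at 78.9 and 102 FPKM in mutants, at least 187-fold higher (limma adjusted p = 1.69e-06), and Sfp93F rose by 5.26. Fbp2 and Fbp1, known for roles in larval fat body, rose by 5.14 and 4.80, and the lysozyme genes LysD and LysB by 5.80 and 4.86. The juvenile hormone binding protein relative dyw rose by 4.69. The deepest falls included CG1304, a serine protease gene at 43.6 and 48.6 FPKM in wildtype with 0 reads in both mutants, at least 278-fold lower, and CG43090, at least 164-fold lower. The trypsin-like genes CG30025, CG30031 and deltaTry had differences of -5.11, -5.05 and -4.67, the antibacterial peptide gene AttA of -4.83 and CG7298 of -4.03. The trypsins form a cluster of close copies that share reads, as do the lysozymes, so the division between members is uncertain. For Acp54A1, CG1304 and CG43090, a difference of stock or samples between mutant and wildtype cannot be told from an effect of the genotype. The same limit applies to the other whole-fly calls.

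Of 34 lists, camera called 16 higher and 6 lower in mutant whole flies. With an estimated correlation 0 were called, and the lowest adjusted p was 0.45. The cuticle list, with an estimated correlation of -0.01, also lost its call. As in muscle, that check cannot tell whether correlation between genes made the calls.

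Most sarcomere genes rose. Of 37 sarcomere genes 25 rose, 0 fell and 12 did not pass, or 27 and 0 adjusted over the list alone, with a median of 0.77 (camera adjusted p = 1.9e-09, adjusted p = 0.45 with an estimated correlation). Act79B, an actin of tubular muscle, rose from 339 and 340 FPKM to 1279 and 1201, and the myosin light chain gene Mlc1 rose by 1.44. Of 6 tubular muscle isoforms 5 rose, with a median of 1.04 (0.0013, adjusted p = 0.45 with an estimated correlation), and of 5 flight muscle isoforms 4 rose, with a median of 1.14 (0.0013, adjusted p = 0.45 with an estimated correlation), the same counts as adjusted over the list alone. The troponin C genes TpnC41C and TpnC4 rose by 1.49 and 1.21 and the flight muscle actin gene Act88F by 1.14. Actin genes are close copies, so reads may be divided between them unevenly.

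Many genes of energy metabolism rose as well. Of 81 nuclear-encoded respiratory chain genes 51 rose, 1 fell and 29 did not pass, or 55 and 2 adjusted over the list alone, with a median of 0.5 (camera adjusted p = 2.4e-09, adjusted p = 0.45 with an estimated correlation). Cytochrome c gene Cyt-c-p rose from 524 and 497 FPKM to 980 and 1040, UQCR-11 by 1.08 and COX7AL2 by 1.45. Of 18 genes of the tricarboxylic acid cycle 11 rose and 0 fell, or 14 and 0 adjusted over the list alone, with a median of 0.43 (2.7e-05, adjusted p = 0.45 with an estimated correlation), led by Pdha at 0.68 and kdn, citrate synthase, at 0.82. Of 17 glycolysis genes 10 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median of 0.49 (2.9e-05, adjusted p = 0.45 with an estimated correlation). The glycerophosphate shuttle genes Gpdh1 and Gpo1 rose by 1.40 and 1.22, and Pfk, phosphofructokinase, by 0.80. Of 21 transcripts of the mitochondrial genome 10 rose and 0 fell, or 12 and 0 adjusted over the list alone, with a median of 0.7 (0.00066, adjusted p = 0.54 with an estimated correlation), among them mt:ATPase6 at 1.60 and mt:ND4L at 1.2, and the whole-fly median was 0.45 without wildtype replicate 2.

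More immune and stress peptide genes fell than rose. Of 28 antimicrobial peptide genes 15 fell, 1 rose and 12 did not pass, or 18 and 1 adjusted over the list alone, with a median of -1.02 (camera adjusted p = 9.3e-07, adjusted p = 0.45 with an estimated correlation). Drsl5 fell from 56.5 and 58.0 FPKM to 11.9 and 13.2, and Drsl4 had a difference of -2.13. All 4 tested Turandot genes fell, also adjusted over the list alone, with a median of -2.23 (0.0013, adjusted p = 0.45 with an estimated correlation), and TotA went from 209 and 170 FPKM to 12.4 and 37.8. TotC and TotM had differences of -2.82 and -1.17.

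Digestive, fat body and cuticle genes changed in both directions. Of 45 digestive enzyme genes 29 fell and 9 rose, or 31 and 11 adjusted over the list alone, with a median of -0.64 (camera adjusted p = 1.3e-05, adjusted p = 0.45 with an estimated correlation). The trypsins fell and the lysozyme LysD rose. Of 45 cuticle genes 20 rose and 3 fell, or 22 and 6 adjusted over the list alone, with a median of 0.58 (4.4e-05, adjusted p = 0.45 with an estimated correlation), among them Cpr100A at 2.66 and Cpr97Ea at 2.49. Of 19 fat body genes 10 rose and 2 fell, as adjusted over the list alone, with a median of 0.57 (2e-04, adjusted p = 0.45 with an estimated correlation), and Obp99b rose from 4.35 and 6.03 FPKM to 155 and 147. Of 11 tracheal genes 5 rose and 0 fell, as adjusted over the list alone, with a median of 0.26 (0.016, adjusted p = 0.66 with an estimated correlation). These were led by verm at 1.91 and serp at 1.73, both chitin deacetylases, and kkv, a chitin synthase, at 1.71. Of 13 hemocyte genes 5 rose, or 6 adjusted over the list alone, with a median of 0.4 (0.0048, adjusted p = 0.45 with an estimated correlation), among them NimB1 at 1.12 and the collagen gene Col4a1 at 0.54. Without mutant replicate 1 the whole-fly medians were 0.07 for fat body and 0.22 for cuticle, and that of cuticle was 0.97 without wildtype replicate 1 and 0.95 without wildtype replicate 2. Such medians also move because members leave a list. Fbp1 and Fbp2, under FPKM 1 in both wildtypes, left the fat body list when either mutant was left out. Over all fat body members the mean log2(FPKM + 1) was 5.99 and 6.06 in mutants and 4.73 and 4.62 in wildtypes. Without mutant replicate 2 the fat body list had a median of -0.01 (adjusted p = 0.21, range over alternatives 3.73e-15 to 0.21) and the tracheal list of 0.21 (adjusted p = 0.104, range 0.000165 to 0.104). Without wildtype replicate 2 the tracheal list had a median of 0.17 and the hemocyte list of 0.21 (adjusted p = 0.0504, range 0.000905 to 0.0504), and Col4a1 no longer passed (adjusted p = 0.0997).

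Some genes of the ovary and eggshell rose and some genes of the testis fell, while many in each list did not pass. Of 19 eggshell genes 10 rose and 0 fell, or 14 and 0 adjusted over the list alone, with a median of 1.07 (camera adjusted p = 9.3e-07, adjusted p = 0.45 with an estimated correlation). The vitelline membrane genes Vm32E and Vm34Ca rose by 2.48 and 1.5. Of 19 ovarian germline genes 6 rose and 0 fell, as adjusted over the list alone, with a median of 0.36 (2e-04, adjusted p = 0.45 with an estimated correlation), among them otu at 0.69. Of 4 yolk and female fat body genes 2 rose, as adjusted over the list alone, with a median of 0.52 (0.0069, adjusted p = 0.45 with an estimated correlation). The female-enriched gene fit rose by 4.43 and the yolk protein gene Yp2 by 0.77. Because fit was under FPKM 1 in both wildtypes, it was no longer a tested member when either mutant was left out. The call of that list ended without mutant replicate 1 (0.16, adjusted p = 0.122) and without mutant replicate 2 (0.39, adjusted p = 0.104), in a range from 8.05e-05 to 0.122. Of 31 testis genes 14 fell and 0 rose, or 17 and 0 adjusted over the list alone, with a median of -0.37 (9.3e-07, adjusted p = 0.45 with an estimated correlation), led by Mst84Dd at -2.12 and Mst84Dc at -1.56. The accessory gland list was not called, with 7 higher and 4 lower of 32, as adjusted over the list alone, a median of 0.07 and an adjusted p of 0.34.

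Some clock genes fell, no neuronal gene passed, and few genes of RNA and protein processing did. Of 12 clock genes 5 fell and 0 rose, or 7 and 0 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.0017, adjusted p = 0.45 with an estimated correlation). The clock gene tim fell from 25.9 and 24.1 FPKM to 12.2 and 13.1, and Pdf and vri had differences of -0.79 and -0.73. Of 19 neuronal genes 0 passed, also adjusted over the list alone, with a median of -0.21 (0.024, adjusted p = 0.76 with an estimated correlation) and values of -0.50 for unc-13 and -0.29 for nSyb. Under some alternatives unc-13 did pass, with limma-voom (adjusted p = 0.0171), summed reads (limma adjusted p = 0.0481) and the replicate number as a block (limma adjusted p = 0.0368). Of 37 spliceosome genes 3 rose and 1 fell, or 1 and 1 adjusted over the list alone, with a median of 0.18 (0.014, adjusted p = 0.7 with an estimated correlation). LSm7 rose by 1.47 and Sf3b3 had a difference of -0.85. Of 48 proteasome genes 5 rose and 2 fell, or 3 and 2 adjusted over the list alone, with a median of 0.25 (0.012, adjusted p = 0.74 with an estimated correlation), with Rpt2 at 0.59 and the testis-expressed Rpn12R at -0.72. Without wildtype replicate 1 the calls of the proteasome (0.19, adjusted p = 0.212), the spliceosome (0.13, adjusted p = 0.148) and the neurons (-0.15, adjusted p = 0.341) ended, as did those of Rpt2 (adjusted p = 0.0764) and Rpn12R (adjusted p = 0.0741). Without mutant replicate 1 the spliceosome (0.07, adjusted p = 0.122) and the neurons (-0.13, adjusted p = 0.324) were not called, and the proteasome had a whole-fly median of 0.14. Neurons were at -0.34 without wildtype replicate 2 and at -0.35 without mutant replicate 2. With the replicate number as a block none of these lists was called (camera adjusted p = 0.128 for the proteasome, 0.0967 for the spliceosome and 0.143 for the neurons). The neurons also lost their call at a minimum FPKM of 5 (camera adjusted p = 0.0967). Across alternatives the adjusted p ranged from 0.000828 to 0.212, 0.00109 to 0.148 and 0.00208 to 0.341 for the proteasome, the spliceosome and the neurons. The splicing regulators were not called in whole flies, with 2 of 44 higher, 0 lower and 0 adjusted over the list alone, a median of 0 and an adjusted p of 0.71. The regulators that rose were x16, by 0.63, and Doa, by 0.41, with 0.48 and 0.41 without wildtype replicate 1. Neither passed with no filter (limma adjusted p = 0.0785 and 0.0704) or with moderation without a trend (0.0548 and 0.0587). Doa also did not pass with the replicate number as a block (limma adjusted p = 0.0631).

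The remaining lists held genes that changed but were not called as groups. Of 58 cytochrome P450 genes 14 rose and 13 fell (median -0.04, adjusted p = 0.54), or 14 and 18 adjusted over the list alone, with Cyp6a8 at 2.80 and Cyp6a2 at -2.70. Of 29 glutathione transferases 2 rose and 7 fell (0.01, 0.27), or 3 and 7 adjusted over the list alone, with GstS1 at 1.73 and GstE5 at -1.59. Odorant binding proteins had 9 higher and 5 lower of 27 (0.12, 0.21), or 9 and 6 adjusted over the list alone, and Obp49a stood at -1.56, and the list was called at 0.13 without whole-fly wildtype replicate 2. Heat shock genes had 4 higher and 2 lower of 12 (0.14, 0.28), or 5 and 2 adjusted over the list alone, with Hsp23 at 1.29, and antioxidants 3 and 2 of 18 (0.07, 0.59), or 6 and 4, with Prx6b at 1.54 and Keap1 at -1.05. Phototransduction genes had 3 higher and 4 lower of 21 (-0.14, 0.43), or 4 and 4, insulin and FoxO genes 2 and 1 of 18 (-0.06, 0.42), with the same counts adjusted over the list alone, and tobi, a glucosidase gene downstream of insulin signalling, at -1.90. Calcium handling and excitation had 2 higher and 1 lower of 15 (-0.03, 0.91), or 4 and 1, with SERCA at 0.79, autophagy 1 and 2 of 21 (0.09, 0.62), with the same counts, and the cytoplasmic ribosome 2 and 0 of 92 (-0.02, 0.95), or 0 and 0. Under quantile scaling the ribosome list was called lower in whole flies, at -0.15. The medians of the calcium, ribosome and glutathione transferase lists differed in sign from their means.

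**Figure D3:**
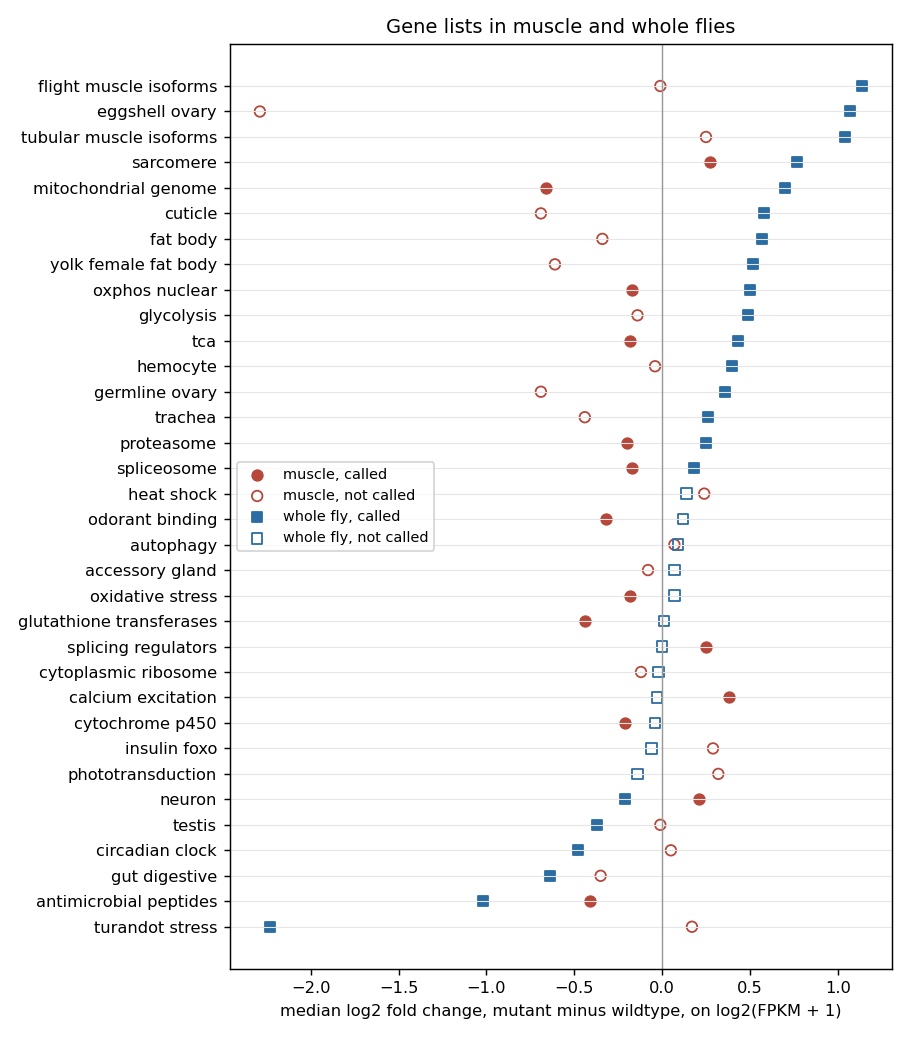
Median log2 fold change of each of 34 gene lists (horizontal axis, mutant minus wildtype on log2(FPKM + 1)) in muscle (red circles) and whole flies (blue squares), filled where camera called the list at a preset correlation of 0.01. The sarcomere list has medians of 0.27 and 0.77, and respiratory chain genes of -0.17 in muscle, which quantile scaling turned to 0.08, and 0.5 in whole flies. With an estimated correlation 0 lists are called in either tissue.

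The last question was whether the genotype effect differed between muscle and whole flies. Taken as whole fly minus muscle, the difference was positive for energy metabolism, contractile and cuticle genes and negative for splicing regulators, neuronal genes and calcium handling genes. It gives a sign and not a size, since neuronal genes had medians of 0.21 in muscle and -0.21 in whole flies. At a preset correlation 21 of 34 lists differed, and with an estimated correlation 0 did, the lowest adjusted p being 0.4. By the limma interaction term 552 of 9465 genes differed, 401 with a positive and 151 with a negative difference, and 2580 had an unadjusted p under 0.05. That fit takes 1 spread per gene over both tissues, although replicates were further apart in muscle. The same fit called 267 muscle genes where muscle alone gave 0, so p-values of the interaction may be too small. Respiratory chain genes differed by a median of 0.72 (camera adjusted p = 9.2e-14, adjusted p = 0.4 with an estimated correlation). LysD had log2 differences of -4.89 in muscle and 5.80 in whole flies (limma adjusted p of the interaction = 0.0038), CG7916 of 3.78 and -0.40 (0.0014), CG17571 of 2.02 and -2.04 (0.0014), CG31313 of -0.75 and 1.52 (0.0038) and gammaTry of -1.79 and -5.28 (0.0014). Wildtype LysD stood at 3624 and 2738 FPKM in muscle but at 1.16 and 1.89 in whole flies. The mutants were closer, at 161 and 68.9 in muscle and 165 and 116 in whole flies. For LysD, a difference between the wildtype samples can therefore not be told from a genotype effect that differs by tissue.

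The count of differing genes moved with single libraries. Without a whole-fly library it was 11 (wildtype replicate 1), 17 (wildtype replicate 2), 13 (mutant replicate 1) or 118 (mutant replicate 2), and without a muscle library 214 (wildtype replicate 1), 293 (wildtype replicate 2), 1526 (mutant replicate 1) or 1690 (mutant replicate 2). Because muscle had 0 calls by limma, 0 genes were called in both tissues. Without muscle mutant replicate 1 there were 4, ClC-a higher and CG14125, CG7567 and CG9029 lower, against 0.103 and 1.06 from independent lists. Across the 9465 genes, which are not independent replicates, the effects in the tissues had a Pearson correlation of -0.171 and a Spearman correlation of -0.231, and 40.7% had the same sign. Single libraries moved these values. Without muscle mutant replicate 1 they were -0.042 and -0.085, nearest to none. The lowest were a Pearson correlation of -0.201 without muscle mutant replicate 2 and a Spearman correlation of -0.271 without whole-fly mutant replicate 2.

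Genes with an unadjusted p under 0.05 in muscle were also set against the whole-fly calls, a comparison added after the data were seen. Higher in both were 63 genes, against 40.5 from independent lists (1-sided Fisher's exact p = 0.000226), and lower in both 85 against 90.6 (Fisher's exact p = 0.761). Lower in muscle and higher in whole flies were 136 against 88.6 (Fisher's exact p = 9.22e-08), and the reverse 59 against 41.5 (Fisher's exact p = 0.00313). Genes are not independent, so these p-values are too small.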

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

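For the muscle region on 3L, its borders and the tests of it were chosen only after the result was seen, as were the tests of other-tissue RNA and of a smaller share of males and the choice of muscle genes with a single wildtype library, while the remaining tests were written before their values were known.

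Lower RNA of neighbouring genes on 3L in muscle mutants (12486668 to 13301922) was weighed first. Chance clustering of unrelated genes does not account for it, since 0 of 1000 shuffles of fold changes over positions gave a window as low as -1.25, the lowest being -0.66. Whether loss of 1 of 2 gene copies alone could give it stays open, because the median ratio was 0.462 (95% interval 0.398 to 0.554) with the borders as drawn, but 0.445 (0.365 to 0.489) and 0.375 (0.331 to 0.459) with 5 and 10 genes trimmed from each end, and 21 of the 66 genes were under 0.4 in both mutants, while sti was at 11.1 and 9.27. Near the right border, CG17300, CG11251, CG32119 and SP had ratios of 4.17, 3.61, 3.23 and 2.88 in mutant replicate 1. In mutant replicate 2 they were at 0, 0, 0.0197 and 0. The interval with the borders as drawn thus includes genes in which the mutants differed, and both trimmed intervals lay under 0.5. A lesion that the whole-fly mutants carry too is not borne out, with a ratio of 1.0 (0.906 to 1.067) in whole flies. Because that leaves a difference between the muscle and whole-fly mutant stocks or samples as a candidate, the region cannot be tied to the genotype.

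The gene lists called in muscle mutants were weighed against technical causes. A gene length trend between libraries could account for part of them, since 5 of 14 kept their call with the trend removed, a number between the predictions of at most 4 and at least 10. Other-tissue RNA in muscle mutant replicate 1 is not borne out as the main cause, since 11 of 14 kept call and direction without that library, though without mutant replicate 2 only 7 did. A smaller share of gut and fat body RNA in mutant muscle, with digestive enzymes at 2.22% and 1.41% of reads against 2.75% and 3.38%, was not tested as a cause and stays open. An effect of the genotype itself remains possible for the lists that kept their call, but with an estimated correlation 0 of the 14 were called. That check can hardly call a list with so few libraries.

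Muscle and respiration genes higher in whole-fly mutants may come from a larger share of muscle tissue in the mutant flies, since 191 genes at least 4 times higher in wildtype muscle than in wildtype whole flies had a median log2 difference of 0.76 (0.63 to 0.86), with 87.4% above 0. That choice shares its whole-fly wildtypes with the fold change, which raises the median. Genes chosen with 1 wildtype library and measured against the other had medians of 0.76 and 0.7, but this removes only the noise of a single library. Genes low in both whole-fly wildtypes, such as LysD (1.16 and 1.89 FPKM, against 3624 and 2738 in wildtype muscle), are still chosen and scored as rises. Separately scaled FPKM values are also compared, so a larger share of muscle cannot be told from a difference between the wildtype samples. Calcium handling and excitation genes did not rise as a list (-0.03), though 1 of 14 compared was so enriched in muscle. A gene length trend between libraries is not borne out, since 6 of 6 lists kept their call with it removed. A smaller share of males in the mutant pools stays open, because accessory gland genes went both ways (median 0.07, 10th to 90th percentile -0.48 to 1.22) while testis genes fell (-0.37) and eggshell genes rose (1.07), as does higher expression per muscle cell through the genotype.

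The genotype effect differed between the tissues for 21 lists and 46 named genes by the interaction test, and each value below is the effect in whole flies minus that in muscle (log2), with its limma or camera adjusted p. With the replicate number as a block, only 4 of 9465 genes were called, so most of these gene calls depend on leaving that block out. Their adjusted p-values also rest on a spread shared by both tissues, although muscle replicates were further apart, and may be too small. Lists with a positive difference were eggshell (3.7, 0.044), cuticle (1.91, 0.00016), mitochondrial genome (1.43, 3e-06), tubular muscle isoforms (0.83, 0.015), glycolysis (0.75, 2.1e-06), fat body (0.73, 0.015), respiratory chain (0.72, 9.2e-14) and tricarboxylic acid cycle (0.62, 9.7e-07). Further lists on that side were antioxidants (0.46, 0.049), proteasome (0.44, 0.0019), odorant binding (0.44, 0.026), sarcomere (0.42, 0.0075), hemocyte (0.41, 0.049) and spliceosome (0.32, 0.0097). The muscle medians behind these values moved with single libraries, that of eggshell to 0.44 without muscle wildtype replicate 1 and -4.52 without muscle wildtype replicate 2, and that of cuticle to -0.1 without muscle mutant replicate 2. On the other side were Turandot genes (-2.41, 0.0058), digestive enzymes (-0.6, 0.0066, with a muscle median of 0.06 without muscle mutant replicate 2), clock (-0.48, 0.037), neurons (-0.42, 0.0015), calcium handling and excitation (-0.37, 0.0097), insulin and FoxO (-0.37, 0.017) and splicing regulators (-0.3, 0.0031). With an estimated correlation 0 of these lists were called, the lowest adjusted p being 0.4.

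Genes with a positive difference were LysD (10.69, 0.0038), LysB (8.48, 0.0087), Cpr92F (7.67, 0.03), dyw (5.59, 0.013), Fbp1 (4.99, 0.013), Obp99b (4.81, 0.013), fit (4.66, 0.013), mt:tRNA:Gln-TTG (3.96, 0.013), Cyp6a8 (3.72, 0.038), Pmm2 (2.54, 0.0063), CG31313 (2.27, 0.0038), TpnC47D (2.12, 0.0066), Cyp6g2 (2.06, 0.012) and Atg12 (2.04, 0.0073). They also included mt:ATPase8 (1.98, 0.035), COX7AL2 (1.93, 0.0084), LSm7 (1.87, 0.031), CG34242 (1.62, 0.0084), TpnC4 (1.54, 0.018), SmD1 (1.53, 0.031), Mlc1 (1.47, 0.018), UQCR-11 (1.44, 0.013), Sf3a2 (1.43, 0.0092), Gpdh1 (1.37, 0.013) and Act79B (1.36, 0.029). The remaining genes on that side were Cyt-c-p (1.25, 0.013), Gpo1 (1.25, 0.018), TpnC41C (1.24, 0.039), CG7054 (1.19, 0.019), GstE9 (1.13, 0.022), ND-SGDH (1.07, 0.013), Cyp4e1 (1.07, 0.021), ND-B17 (0.95, 0.027), Pdha (0.68, 0.037) and Pfk (0.67, 0.031). The difference was negative for AttA (-5.45, 0.021), CG7916 (-4.18, 0.0014), CG17571 (-4.06, 0.0014), CG30025 (-3.93, 0.0087), CG30031 (-3.92, 0.0084), CG31343 (-3.64, 0.0038), gammaTry (-3.5, 0.0014), deltaTry (-2.88, 0.0038), GstE5 (-1.45, 0.018), Drsl5 (-1.25, 0.04) and CG12057 (-1.09, 0.041). Pmm2, CG34242, Sf3a2 and SmD1 lie in the 3L region, whose median ratio was 0.462 in muscle and 1.0 in whole flies. ND-SGDH and Atg12 lie in a further 3L stretch of lower muscle RNA, given under other observations. In whole flies mt:tRNA:Gln-TTG had 0 reads in both wildtypes and only 2 and 5 in the mutants. LysD stood at 3624 and 2738 FPKM in wildtype muscle but at 1.16 and 1.89 in wildtype whole flies, so its wildtype samples differed most.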

How the results depend on the processing

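The tests on recovered reads, summed reads, protein-coding entries and gene length were chosen only after the first results were seen. Of the muscle gene counts, 0 held under pseudocounts of 0.1 and 5, no filter, trimmed-mean scaling, no trend, limma-voom and summed reads. The count was 2 at a minimum FPKM of 5, under quantile scaling, for protein-coding entries and with the length trend removed, and 267 in a fit over all 8 libraries, which shares the smaller whole-fly spread. It was 12 without mutant replicate 1 and 0 without each of the other libraries. With either mutant left out, w, CG7916, CG12057 and CG31343, under FPKM 1 in both wildtypes, were not tested, so these fits do not bear on them. Of the 14 muscle lists 5 were called with the length trend removed and 0 with an estimated correlation. Quantile scaling reversed the tricarboxylic acid cycle list to 0.02 and the respiratory chain list to 0.08, and the proteasome list was at 0.02 without mutant replicate 2 and at -0.38 without mutant replicate 1. The cause was not tested.

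In whole flies the count of genes lay between 1779 and 2812 under the other settings, 1409 without wildtype replicate 1, 1512 without wildtype replicate 2, 1710 without mutant replicate 1, 3213 without mutant replicate 2 and 546 in the fit over all 8 libraries. With an estimated correlation 0 of the 22 lists were called. Genes seen in 1 genotype alone, such as Acp54A1 and CG1304, were not tested when a library of that genotype was left out. Of 91 called named genes 17 lost their call without a library and 8 under another setting, and 0 reversed. With a library left out, the interaction count ranged from 11 without whole-fly wildtype replicate 1 to 1690 without muscle mutant replicate 2. The overlap was 4 without muscle mutant replicate 1 and 0 without each other library. Recovery of 4% of simulated 2-fold changes limits what muscle calls can show.

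Samples of different genotype share only a replicate number, and same-numbered deviations correlated at 0.39 in muscle and -0.15 in whole flies. With the replicate block, muscle had 0 genes and 17 lists, whole flies 2807 genes and 21 lists, the interaction 4 genes and the overlap 0. Of the 22 whole-fly lists 19 kept their call and 2 calls were new, while the proteasome, spliceosome and neuron lists lost theirs.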

Other observations

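The genes and regions below were chosen only after their values were seen, and no explanation of them was tested.

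The 4 larval serum protein genes were higher in mutant whole flies by limma. Lsp2 went from 0.0613 and 0.0385 FPKM to 6.24 and 9.64 (adjusted p = 0.000156), and Lsp1beta, Lsp1alpha and Lsp1gamma rose by 2.21, 1.87 and 1.8 (log2). The long noncoding RNA lncRNA:CR46350 (3R, 9283875 to 9284525) had 38 and 29 reads in wildtype whole flies and 0 in both mutants (adjusted p = 0.00103), and 23 and 25 reads in wildtype muscle and 0 in both mutants (adjusted p = 0.287). In whole flies the w gene had 5 and 20 reads in wildtype and 24 and 29 in mutant and was too low to be tested.

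Some stretches of neighbouring genes held more genes that fell than rose in whole-fly mutants by limma, and they were not tested as gene lists. Of 8 tested Osi genes 6 fell and 0 rose, with a median of -1.58 (log2), and of 8 Mal-A maltase genes 7 fell and 1 rose, with a median of -0.77. A stretch of 2R from 17861273 to 18139990 held 25 tested genes, of which 10 fell, 2 rose and the median was -0.17, and the stretch with the trypsin cluster at 11294536 to 11370287 held 23, of which 11 fell, 2 rose and the median was -0.2. In muscle the lowest windows of 15 genes outside the 3L region lay on 2R from 18188978 to 18390629 (median -0.74), with bomanin genes, and on 3R from 12231645 to 12380815 (-0.69), with glutathione transferase genes, inside longer stretches of 29 and 22 genes with medians of -0.57 and -0.19. Overlapping windows on 3L, from 12121274 to 12190705 and from 12129393 to 12199030, had medians of -0.58, and 19 of 1000 shuffles gave a window as low. ND-SGDH and Atg12 lie in both. No gene of these muscle stretches was called by limma.

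Without muscle mutant replicate 1, limma called 12 muscle genes. Besides those named in the report these were LysB (-4.17), LysE (-3.64), Mco4 (-3.29), CG31287 (-3.6), CG7567 (-3.05), CG12934 (-3.52), CG9029 (-4.24) and mt:tRNA:Leu-TAG (-4.08). In whole flies CG12934 rose by 3.56 (adjusted p = 2.37e-05).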
